A study of Mus musculus with 8 samples.

How the data were processed

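RNA was measured by sequencing in first molars of mouse pups, from which the pulp had been removed, per the labels' protocols. The labels name the samples as enamel organ cells and ameloblasts, the epithelial cells that form enamel, from C57BL/6 mice. The remaining molar was homogenised whole, so that other tissue left on the molar could enter the RNA. There were 4 wild-type libraries (WT 2, 3, 4 and 5) and 4 libraries from mice lacking Wdr72 (KO 1, 3, 4 and 5), numbered as in the labels. The age label gives postnatal day 12 and the dissection protocol gives day 13, and the difference could not be settled here. The labels do not say whether each library came from 1 pup or from a pool, and most libraries held both Xist and Y-linked reads, so the p-values measure only the spread between these libraries.

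The authors deposited 1 table of counts, the number of reads per Ensembl gene in each library, whole numbers that were not normalised. RNA went through polyA capture before fragmentation and reverse transcription, per the labels' protocols. The submitters' processing notes name CASAVA and the build mm39. The aligner, the counting program and its strand setting are not given in the sources used here. The coordinates in the table are those of GRCm38 and not of mm39: of 54532 gene IDs, 54495 were also in GENCODE M21, and 98.8% of these had the same start. Coordinates are therefore given on GRCm38, as in the deposited table. Gene lengths in the table were also the authors'. Without a known strand setting, reads of overlapping genes cannot be told apart. Of the 84 genes named by the rule below, 27 overlapped another gene with reads, and in 12 of these the overlapping gene had over 10% as many reads as the named one.

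The libraries held 17084475 to 21887462 counted reads. Genes with too few reads were left out with filterByExpr (minimum count 10, minimum total 15), which left 16205 of 54532 genes, of which 14250 were protein-coding; 22656 genes had no read in any library. The kept genes held 99.8% to 99.9% of the reads of each library. TMM factors lay between 0.936 and 1.06. Levels are given as CPM, a gene's reads relative to the TMM-scaled total of its library, computed here from the deposited counts, as mean ± SD over 4 libraries. The biological coefficient of variation was 17.8%.

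KO was compared with WT by edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust dispersion), two-sided, with no covariate and Benjamini-Hochberg adjustment over all genes tested. The threshold was an adjusted p of 0.05. Log2 fold changes are KO minus WT, and SE was taken as the size of the log2 fold change divided by the square root of the F statistic. Gene lists were tested by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over 35 lists, and again with the correlation estimated from the data. The fry test was run beside it. For each list the members past 0.05 were counted over all genes and adjusted over the list alone. An exact permutation test of each list's mean log2 CPM per library over the 70 arrangements, two-sided, was added after the data were examined. The smallest p it can give is 0.0286, so after adjustment over 35 lists it could hardly pass 0.05.

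The lists, the tests, the rule for named genes and most alternatives were set before the data were examined. They covered enamel matrix, maturation ameloblasts, pH and ion transport, the V-ATPase, the rabconnectin complex, calcium, endocytosis, exocytosis, lysosomes, iron, tight junctions, the unfolded protein response, cell cycle, immediate early genes, circadian clock, interferon response, glycolysis, Wnt and BMP signalling, stratum intermedium and papillary layer, and markers of odontoblasts, pulp mesenchyme, osteoclasts, macrophages and leukocytes, neutrophils, erythroid cells, endothelial and mural cells, nerve and Schwann cells, skeletal muscle, oral keratinocytes, adipose and salivary tissue, and cartilage. The remaining lists were nuclear respiratory chain genes, ribosomal proteins, mitochondrially encoded genes and genes within 5 Mb of Wdr72. Sex-linked genes were reported as values. The rule named Wdr72, up to 8 protein-coding genes per direction with the largest changes past the threshold, a mean of at least 2 CPM and no overlap between groups, the 4 with the smallest p per direction under the same conditions, up to 4 members of each list past the threshold or otherwise the 2 with the smallest p, and 14 genes fixed by name. Of the genes that the rule names, 3 are not reported here. Other list members named in the text, and the genes of the closing part that passed only an adjusted p of 0.1, were chosen after their values were seen.

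The alternatives were other scalings (DESeq2 size factors, upper quartile, library totals), other tests (DESeq2 1.42.0, limma voom with quality weights), other filters, covariates, 1 surrogate variable (sva 3.50.0), a block on the replicate number, and each library left out in turn. A keratinocyte covariate, a GC and length correction, leaving out KO 1 and KO 5 together, and an adjusted p of 0.1 were added after the data were examined. Before any average, the libraries were compared pairwise by a chi-square test over genes with at least 400 reads in all libraries together, and no pair agreed within sampling noise (lowest chi-square per gene 14.7, between WT 5 and KO 4). The gene test was tested on simulated counts for these 16205 genes, with 200 genes changed in each of 3 runs: 23.4% of genes changed 1.5-fold were recovered, 72.1% of those changed 2-fold and 93.4% of those changed 4-fold, with 4.56% false calls. In the simulation each gene varied independently, with no shift shared across a library, so these shares may be too high for the real libraries. Plots were drawn with matplotlib 3.10.9.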

Results

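Gene expression was compared between first molars of wild-type mice and of mice with an ablated Wdr72 gene, at the stage when enamel matures. WDR72 is a WD40-repeat protein whose loss is known to cause hypomaturation amelogenesis imperfecta, a defect of enamel mineralisation. The design compared 4 WT with 4 KO libraries. The libraries held 17084475, 20789225, 21505301 and 17378714 reads in WT 2, 3, 4 and 5, and 18430132, 21887462, 21556336 and 20570505 in KO 1, 3, 4 and 5. The 10 most abundant genes took 14.3% to 16.9% of the reads. They included Ambn (3.74% of all reads), Odam (2.20%) and Amelx (0.672%), which encode proteins of the enamel organ, and Col1a1 (2.53%), Col1a2 (1.74%) and Dspp (1.33%), which are abundant in the cells that make dentin and bone. 

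Wdr72 (ENSMUSG00000044976), on chromosome 9 from 74110356 to 74283308, was lower in each KO library than in each WT library. Its level was 243 ± 63.6 CPM in WT and 45.1 ± 38.9 CPM in KO (SD, n = 4 each), or 18.5% of the WT mean. The WT libraries had 173, 245, 327 and 227 CPM, and KO 1, 3, 4 and 5 had 102, 37.8, 24.9 and 15.8 CPM. KO 1 thus held 41.9% of the WT mean and KO 5 held 6.50%. The log2 fold change was -2.43 (SE 0.47). The exact permutation test over 70 arrangements, two-sided, gave p = 0.0286, the smallest it can give. In edgeR the adjusted p over all genes was 0.080, which did not pass 0.05. Without KO 1 the log2 fold change was -3.21 with an adjusted p of 0.012 in edgeR, and over all alternatives the adjusted p ran from 0.0035 to 0.99. The labels do not say which part of the gene was deleted, so counts over the whole gene check the labels only by level.

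Over all genes, 5 of 16205 changed in KO against WT by edgeR's quasi-likelihood test, 2 higher and 3 lower. Spink5, a serine protease inhibitor of stratified epithelia (chromosome 18, 43963235 to 44022501), fell from 5.21 ± 1.40 to 1.03 ± 0.235 CPM (log2 fold change -2.33, SE 0.27, adjusted p = 0.027). Krt1, a keratin of differentiating keratinocytes (chromosome 15, 101845426 to 101850794), fell from 9.96 ± 6.02 to 1.60 ± 0.232 CPM (log2 fold change -2.64, SE 0.36). Ak4, a mitochondrial adenylate kinase (chromosome 4, 101419277 to 101466995), fell from 16.8 ± 2.60 to 7.90 ± 0.910 CPM (log2 fold change -1.09, SE 0.15). AI593442, which lies on chromosome 9 as Wdr72 does, from 52673042 to 52679780, rose from 3.29 ± 1.21 to 14.5 ± 4.69 CPM (log2 fold change 2.14, SE 0.30). Smpd3, a neutral sphingomyelinase of mineralising tissue (chromosome 8, 106252548 to 106337988), rose from 40.3 ± 3.78 to 67.0 ± 2.85 CPM (log2 fold change 0.73, SE 0.10). The adjusted p was 0.040 for each of Krt1, Ak4, AI593442 and Smpd3, and for all 5 genes the 4 KO values lay apart from the 4 WT values. Smpd3 overlaps Prmt7, which had 50.1% as many reads, so its count is uncertain.

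The count of changed genes was not stable when a single library was left out. By edgeR it was 0 without WT 2, WT 3, KO 3 or KO 4 (1744, 1720, 3139 and 2622 genes at an unadjusted p of 0.05), 16 without WT 4 and 55 without KO 5. A fit with fewer libraries also has less power, so these counts do not show that the result hangs on any single library. Without WT 5 or KO 1 it was 5 each, of which 3 and 2 were among the 5 genes above. At an unadjusted p of 0.05 there were 2541 genes, against 810 expected by chance if genes varied independently and up to 1785 in other splits of the same 8 libraries, and 1774 genes (10.9%) had groups that did not overlap, against 2.86% by chance. DESeq2 called 465 genes and limma voom 1073 at the same threshold.

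**Figure D1:**
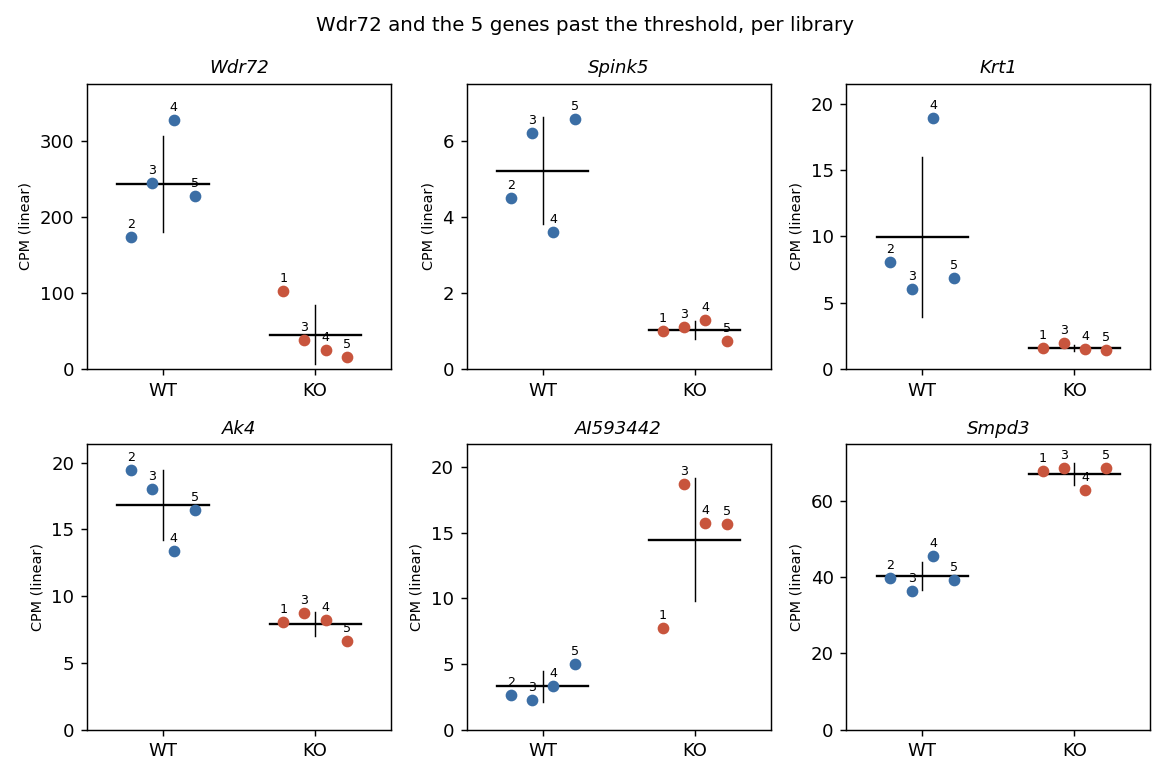
Level of Wdr72 and of the 5 genes past the threshold in each library, in CPM on linear axes that start at 0, with replicate numbers beside the points; horizontal lines are group means and vertical lines 1 SD (n = 4). KO 1 holds 102 CPM of Wdr72, between the other KO libraries and WT, and the points of the groups do not overlap in any panel.

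Genes of oral keratinocytes were the list that moved most. All 16 tested members were lower in KO, with a median log2 fold change of -1.03, and the list fell in camera (adjusted p = 3.1e-11 with the preset correlation, adjusted p = 0.48 with an estimated correlation). Over all genes 1 member passed, Krt1, and 12 passed adjusted over the list alone. Krt6b was at 127 ± 57.5 CPM in WT and 36.8 ± 4.11 CPM in KO, Krt13 at 61.1 ± 4.33 and 24.0 ± 14.3 CPM, and Krtdap, a keratinocyte differentiation protein, at 6.71 ± 2.94 and 1.53 ± 0.56 CPM. Krt6b and Krt6a are close paralogs, so their counts are uncertain. The mean log2 CPM of the list lay at 4.29 to 4.998 in the WT libraries and at 3.42 to 4.13 in the KO libraries. The exact permutation p was 0.0286, the smallest it can give, with an adjusted p of 0.20 over 35 lists. The Xist level also differed between the groups, at 637 ± 269 CPM in WT and 243 ± 81.4 CPM in KO, with an adjusted p of 0.12 in edgeR. The Spearman correlation across genes of a library's deviation with GC content lay between -0.42 and -0.16 in the WT libraries and between -0.051 and 0.37 in the KO libraries.

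The lists of enamel genes did not pass as tested here. The enamel matrix list (14 tested) had a median log2 fold change of 0.13 and an adjusted p of 0.21 in camera, and 0 members passed in edgeR over all genes or adjusted over the list alone (1 at an unadjusted p of 0.05). With no low-count filter the list passed, at a median of 0.15 (adjusted p = 0.029), and over the alternatives its adjusted p ran from 0.029 to 0.96. Amelx, which encodes amelogenin, was at 5423 ± 1933 CPM in WT and 7987 ± 2289 CPM in KO (log2 fold change 0.56, SE 0.27). Ambn was at 38662 ± 12366 and 35754 ± 5586 CPM. Mmp20, the protease of secretory enamel, was at 330 ± 64.7 and 340 ± 51.7 CPM. Enam varied widely, from 50.2 to 326 CPM in WT and from 109 to 832 CPM in KO (log2 fold change 1.41, SE 0.81). Itgb4, an integrin of the basement membrane, had a log2 fold change of 0.37 (SE 0.11) and an adjusted p of 0.18 in edgeR.

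The maturation ameloblast list (23 tested) had a median log2 fold change of 0.0012 and an adjusted p of 0.68 in camera, with 0 members past either threshold in edgeR (2 higher and 2 lower at an unadjusted p of 0.05). Klk4, the protease that clears enamel matrix, was at 1895 ± 349 CPM in WT and 1682 ± 246 CPM in KO, Amtn at 5085 ± 1573 and 5587 ± 814 CPM, and Odam at 22608 ± 3177 and 21352 ± 1343 CPM. The log2 fold change was -0.32 (SE 0.18) for Slc24a4, a calcium exchanger, -0.76 (SE 0.26) for Itgb6 and -0.60 (SE 0.22) for Slc26a7, an anion exchanger. The stratum intermedium and papillary list (13 tested) had a median of -0.0055 and an adjusted p of 0.81. In that list Thbd had a log2 fold change of -0.35 and Slc2a1, a glucose transporter, of -0.49.

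Lists of acid, ion and vesicle transport, the processes to which WDR72 has been linked, did not pass either. The V-ATPase list (21 tested) had a median log2 fold change of 0.083 and an adjusted p of 0.55 in camera. Its members with the smallest p were Tcirg1, at 0.53 (SE 0.15), and Atp6v0a4, at -0.65 (SE 0.26), whose count is uncertain because it overlaps a gene with more reads. The rabconnectin list had a median of -0.13 over 4 genes and an adjusted p of 0.68. Without KO 5 the medians were -0.018 for the V-ATPase list and 0.00086 for the rabconnectin list, and with voom they were -0.013 and 0.045, so neither direction held. The log2 fold change was -0.22 (SE 0.21) for Dmxl1, -0.43 (SE 0.21) for Dmxl2, -0.048 (SE 0.15) for Wdr7 and 0.41 (SE 0.17) for Rogdi. The pH and ion transport list (34 tested) had a median of -0.048 and an adjusted p of 0.49, with Slc9a2 at 1.01 (SE 0.25) and Car13, a carbonic anhydrase, at -0.39 (SE 0.12). The calcium list (32 tested) had a median of 0.00030 and an adjusted p of 0.89, with Slc8a2 at 0.91 (SE 0.28) and Orai1, a calcium channel, at 0.65 (SE 0.20). Endocytosis (48 tested, median 0.058, adjusted p = 0.81) and exocytosis (47 tested, median -0.034, adjusted p = 0.49) held Cav2 at -0.45, Ehd1 at 0.47, Stx3 at -0.39 and Exoc7 at 0.26. By edgeR 0 members of these lists passed over all genes or adjusted over the list alone. At an unadjusted p of 0.05 there were 2 V-ATPase genes, 1 rabconnectin gene, 7 pH and ion genes, 3 calcium genes, 12 endocytosis genes and 3 exocytosis genes.

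The lysosome list rose slightly, with 32 of 46 members higher, a median of 0.18 and an adjusted p of 0.020 with the preset correlation (adjusted p = 0.68 with an estimated correlation). It did not pass in 9 of 25 alternatives run with the preset correlation, among them those without WT 2 (adjusted p = 0.067), WT 4 (adjusted p = 0.065) or KO 1 (adjusted p = 0.069). Without KO 1 and KO 5 together its median was 0.056 (adjusted p = 0.34). Its median was 0.12 without KO 5 and 0.072 with the GC and length correction. The exact permutation test of its library means gave p = 0.086 (adjusted p = 0.30). By edgeR it had 0 members past the threshold over all genes or adjusted over the list alone, and 8 higher and 1 lower at an unadjusted p of 0.05. Lamp1 had a log2 fold change of 0.054 (SE 0.13), and the smallest p values were those of Gaa, the acid glucosidase, at 0.54 (SE 0.14) and Gpnmb at 0.41 (SE 0.13). In the iron list (21 tested, median -0.053, adjusted p = 0.89) Steap4, a metalloreductase, passed adjusted over the list alone (log2 fold change 0.73, SE 0.15), and Hmox1 was at 0.32. In the tight junction list (30 tested, median -0.030, adjusted p = 0.55) Cldn4 passed adjusted over the list alone (log2 fold change 1.34, SE 0.33), and Tjp3 was at -0.78, a count that is uncertain because Apba3 overlaps it with more reads. Median, mean and camera direction differed in sign in the iron, maturation ameloblast, calcium, exocytosis, and adipose and salivary lists. The medians of the maturation ameloblast and calcium lists were negative with each other scaling tried.

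**Figure D2:**
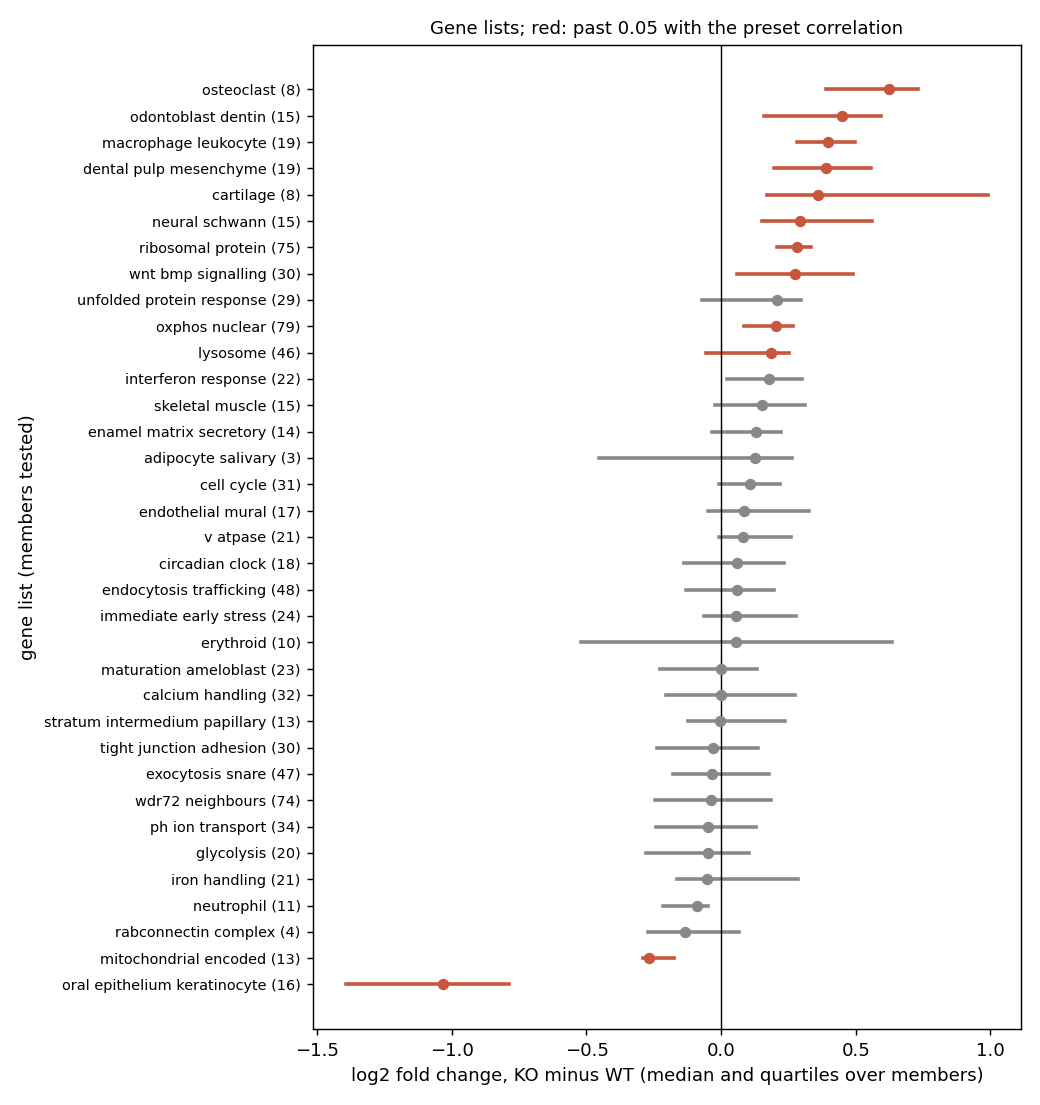
Median log2 fold change (points) and quartiles (bars) over the tested members of each of the 35 gene lists, KO minus WT, with the number of members in brackets. Red marks the 12 lists with an adjusted p under 0.05 with the preset correlation; the keratinocyte list has the lowest median, -1.03.

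Markers of mesenchymal and hard-tissue cells were higher in KO. The pulp mesenchyme list rose by a median of 0.39, with 17 of 19 members higher (adjusted p = 2.9e-05, and adjusted p = 0.57 with an estimated correlation). Over all genes 0 members passed, and 8 passed adjusted over the list alone. Col6a1, a collagen VI chain, was at 129 ± 20.8 CPM in WT and 229 ± 42.3 CPM in KO, Col3a1 at 1940 ± 578 and 3572 ± 838 CPM, and Mfap4 at 22.1 ± 4.44 and 38.9 ± 10.2 CPM. Mfap4 overlaps Mapk7, so its count is uncertain. The odontoblast and dentin list rose by a median of 0.45 (adjusted p = 0.00017, and adjusted p = 0.53 with an estimated correlation), with 1 member past the threshold over all genes, Smpd3, and 6 adjusted over the list alone. Dspp, the main dentin gene, was at 13685 ± 5138 CPM in WT and 13052 ± 4135 CPM in KO. The bone genes Bglap and Bglap2, near-identical copies whose counts are uncertain, had log2 fold changes of 0.66 (SE 0.19) and 0.81 (SE 0.23). The cartilage list rose by a median of 0.36 (adjusted p = 0.012, and adjusted p = 0.57 with an estimated correlation), with 0 members past over all genes and 3 adjusted over the list alone. Without KO 1 and KO 5 the cartilage list did not pass (median 0.31, adjusted p = 0.074). Col2a1 was at 21.1 ± 5.85 and 46.8 ± 16.4 CPM, and Col9a2 at 24.3 ± 2.82 and 46.6 ± 17.1 CPM. KO 5 stood apart from the other libraries, with a mean correlation of 0.965 with them against 0.980 to 0.983 for the rest.

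Genes of Wnt and BMP signalling moved with them. The list rose by a median of 0.27 (adjusted p = 0.0012, and adjusted p = 0.57 with an estimated correlation), with 25 of 30 members higher. The median was 0.12 without KO 5 (adjusted p = 0.0096), and without KO 1 and KO 5 it was 0.097 and did not pass (adjusted p = 0.063). Over the alternatives run with the preset correlation the adjusted p in camera ran from 2.4e-05 to 0.23. Over all genes 0 members passed, and adjusted over the list alone 8 were higher and 1 was lower. Sfrp2, a secreted Wnt antagonist, was at 21.9 ± 6.12 CPM in WT and 44.4 ± 8.47 CPM in KO. Notum, which inactivates Wnt proteins, was at 4.60 ± 0.411 and 9.90 ± 3.23 CPM, and Tcf7, a Wnt-responsive transcription factor, at 14.1 ± 0.775 and 19.8 ± 1.19 CPM. Bmp4 was the lower member, at 130 ± 25.8 and 87.8 ± 10.6 CPM. Adjusted p values in edgeR over all genes were 0.079 for Sfrp2 and 0.085 for Notum.

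**Figure D3:**
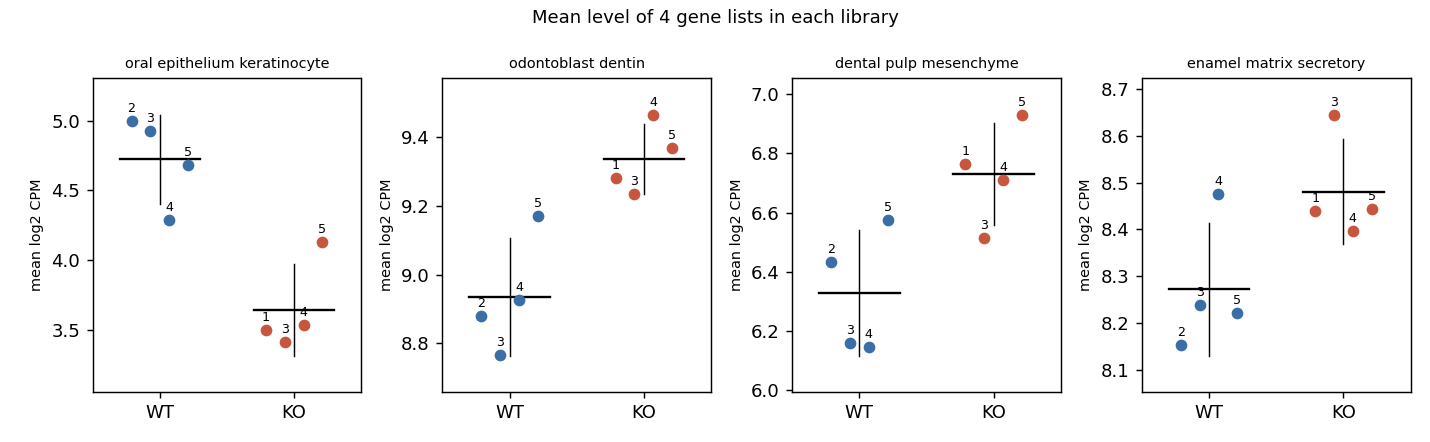
Mean log2 CPM of 4 gene lists in each library, with replicate numbers beside the points, group means as horizontal lines and 1 SD as vertical lines (n = 4); each panel has its own vertical scale, which does not start at 0. The keratinocyte means lie at 4.29 to 4.998 in WT and 3.42 to 4.13 in KO.

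Marker lists of other cell types were also higher in KO. The macrophage and leukocyte list rose by a median of 0.40, with 18 of 19 members higher (adjusted p = 0.00031, and adjusted p = 0.57 with an estimated correlation), 0 members past over all genes and 2 adjusted over the list alone. Its median was 0.24 without KO 5 (adjusted p = 0.0028), and without KO 1 and KO 5 it was 0.17 and did not pass (adjusted p = 0.064). Csf1r, the macrophage growth factor receptor, was at 39.2 ± 3.72 and 51.5 ± 2.05 CPM, and Cd68 at 17.9 ± 1.18 and 24.9 ± 3.76 CPM. Csf1r overlaps Hmgxb3, so its count is uncertain. The nerve and Schwann cell list rose by a median of 0.29 (adjusted p = 0.0025, and adjusted p = 0.48 with an estimated correlation), with 0 members past over all genes and 4 adjusted over the list alone. Its median ran from 0.23 without WT 2 to 0.46 without WT 5. The exact permutation test of its library means gave p = 0.14 (adjusted p = 0.36). Its mean log2 CPM in KO 1 was 2.27, within the WT libraries at 2.23 to 2.55. Tubb3, a neuronal tubulin, was at 34.4 ± 3.70 and 53.0 ± 7.52 CPM. The osteoclast list rose by a median of 0.62 (adjusted p = 0.030, and adjusted p = 0.68 with an estimated correlation), with 0 of 8 members past either threshold in edgeR and 1 at an unadjusted p of 0.05. It did not pass without WT 5 (median 0.43, adjusted p = 0.14), KO 1 (median 0.64, adjusted p = 0.095), KO 3 (median 0.72, adjusted p = 0.059) or KO 5 (median 0.32, adjusted p = 0.13). Mmp9 was at 68.8 ± 23.8 and 114 ± 25.03 CPM, and Acp5 at 73.2 ± 29.9 and 119 ± 50.5 CPM. 

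The neutrophil list (11 tested) had a median log2 fold change of -0.090 and an adjusted p of 0.57 in camera, with Mmp8 at -0.35 and S100a8 at -0.25, and passed without WT 5 (median -0.30, adjusted p = 0.015). It also passed with voom (median -0.45, adjusted p = 0.0088), with the Xist covariate (median -0.58, adjusted p = 0.0043) and without KO 1 and KO 5 (median -0.53, adjusted p = 0.042). Its median turned to 0.049 without WT 3, 0.096 without WT 4 and 0.084 without KO 4. The erythroid list (10 tested) had a median of 0.054 and an adjusted p of 0.81, with Hbb-bs, a haemoglobin chain, at 0.85 (SE 0.37). Its median ran from -0.20 without WT 5 to 0.28 without WT 4. The endothelial and mural list (17 tested, median 0.085, adjusted p = 0.21) held Plvap at 0.48 and Rgs5 at -0.35. The muscle list (15 tested, median 0.15, adjusted p = 0.42) held Acta1 at 0.53 and Tnnt3 at 0.48, and passed without WT 4 (median 0.34, adjusted p = 0.046), while without WT 5 its median was -0.062. The adipose and salivary list had 3 tested members (median 0.13, adjusted p = 0.93), with Plin4 at -1.03 and Fabp4 at 0.40. Plvap, Tnnt3 and Plin4 overlap other genes with reads, so their counts are uncertain. By edgeR 0 members of these lists passed over all genes or adjusted over the list alone, and at an unadjusted p of 0.05 there were 3 erythroid and 7 endothelial or mural genes and 0 in the others.

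Of the lists on metabolism and RNA makeup, ribosomal protein genes rose by a median of 0.28 (72 of 75 higher, adjusted p = 3.2e-05, and adjusted p = 0.86 with an estimated correlation). Nuclear genes of the respiratory chain rose by a median of 0.20 (76 of 79 higher, adjusted p = 0.011, and adjusted p = 0.91 with an estimated correlation). Mitochondrially encoded genes fell by a median log2 fold change of -0.27 (13 of 13 lower, adjusted p = 0.015, and adjusted p = 0.74 with an estimated correlation). The exact permutation test of library means gave p = 0.40 for ribosomal proteins, 0.66 for the respiratory chain and 0.23 for mitochondrially encoded genes. By edgeR 0 members of the 3 lists passed over all genes or adjusted over the list alone, and 2 ribosomal, 1 nuclear and 1 mitochondrial gene had an unadjusted p under 0.05. Rps26 had a log2 fold change of 0.39, Uqcrc1 of 0.39, Ndufa11 of 0.49, mt-Nd5 of -0.59 (SE 0.22) and mt-Nd4l of -0.65, and ribosomal protein genes share reads with their pseudogenes. Ndufa11, mt-Nd5 and mt-Nd4l overlap other genes with reads, so their counts are uncertain. Without KO 5 the median was -0.021 for the respiratory chain list (adjusted p = 0.58) and 0.052 for ribosomal proteins (adjusted p = 0.29). The respiratory chain list also did not pass without WT 2 (adjusted p = 0.079) or WT 5 (adjusted p = 0.13), and its median was 0.31 without KO 3. The mitochondrially encoded list did not pass without WT 4 (median -0.11, adjusted p = 0.33), and with the GC and length correction its median turned to 0.016 (adjusted p = 0.997). Over the alternatives its adjusted p ran from 2.4e-07 to 0.997. In KO 5, genes of short length and high GC content were relatively high, with a Spearman correlation across genes of -0.44 with length and 0.37 with GC content. Genes are not independent replicates in these correlations. The glycolysis list (20 tested) had a median of -0.049 and an adjusted p of 0.12, and Pdk1, which restrains pyruvate use in mitochondria, passed adjusted over the list alone (log2 fold change -0.52, SE 0.10). The glycolysis list passed without WT 4 (median -0.10, adjusted p = 0.028) and without KO 5 (median -0.11, adjusted p = 0.0096), and with no other single library left out. It also passed with voom (median -0.16, adjusted p = 0.0026), DESeq2's Wald test (adjusted p = 0.049) and 1 surrogate variable (median -0.12, adjusted p = 0.0038). Without KO 1 and KO 5 its median was -0.18 (adjusted p = 0.0027).

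The remaining lists did not pass in camera. The unfolded protein response list (29 tested) had a median of 0.21 and an adjusted p of 0.078, with Syvn1 at 0.29, a count that is uncertain because it overlaps Mrpl49, and Xbp1 at 0.47, and passed without KO 1 (adjusted p = 0.022). It also passed in camera with DESeq2's Wald test and with voom (adjusted p = 0.038 each), and without KO 1 and KO 5 (adjusted p = 0.019). In the 6 libraries of the replicate block fit it passed without the block (adjusted p = 0.029) but not with it (adjusted p = 0.052). The immediate early list (24 tested, median 0.057, adjusted p = 0.15) held Egr1 at 0.69 and Egr2 at 1.13. The interferon list (22 tested, median 0.18, adjusted p = 0.085) held Ifit1 at 0.77 and Oas1a at 0.68, and passed without KO 4 (adjusted p = 0.047). Without KO 5 the medians were 0.10 for the unfolded protein response list and 0.099 for the interferon list. The cell cycle list (31 tested, median 0.11, adjusted p = 0.21) held Tyms at 0.24 and Ccne1 at 0.37, and passed without WT 3 (adjusted p = 0.041). The clock list (18 tested, median 0.061, adjusted p = 0.81) held Nfil3 at 0.50 and Bhlhe40 at 0.33. The genes within 5 Mb of Wdr72 (74 tested) had a median of -0.038 and an adjusted p of 0.32, with Aldh1a2 at 0.84 (SE 0.19) and Myo5c at -0.46 (SE 0.15). By edgeR 0 members of these lists passed over all genes or adjusted over the list alone. At an unadjusted p of 0.05 there were 6 unfolded protein, 3 immediate early, 1 interferon, 0 cell cycle, 4 clock and 11 neighbouring genes. With no low-count filter the unfolded protein response (adjusted p = 0.0087), immediate early (adjusted p = 0.025), interferon (adjusted p = 0.0080) and cell cycle lists (adjusted p = 0.040) passed.

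Sex-linked genes differed between libraries. Xist, the RNA made from the inactive X chromosome, was at 803, 839, 251 and 658 CPM in WT 2, 3, 4 and 5 and at 249, 191, 356 and 177 CPM in KO 1, 3, 4 and 5, and passed in edgeR adjusted over the list of 5 tested sex-linked genes alone. The Y-linked gene Ddx3y was at 0.716 CPM in WT 3 and at 22.1 to 83.5 CPM in the other libraries, and Eif2s3y at 1.24 CPM in WT 3. All libraries but WT 3 thus held Xist at 177 CPM or more together with Ddx3y at 22.1 CPM or more. Xist is a marker of female cells and Ddx3y of male cells, so n counts libraries and not pups. Of the 35 lists, 12 passed with the preset correlation and 0 with an estimated correlation, and fry gave 0 lists that moved one way and 8 whose genes changed in either direction. In the exact permutation test of library means the lowest adjusted p of the lists was 0.20. That test can give no p under 0.0286, so its adjusted p has little room to pass and decides on no list. With Xist as a covariate 6 lists passed, of which 4 were among the 12: keratinocyte, odontoblast, pulp mesenchyme and mitochondrially encoded genes.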

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

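The test behind these values, a library whose gap to the nearest of its group is a large share of the group's range, was set before the data were examined. It was run on 176 groups of 4 libraries, the WT and KO groups of the named and sex-linked genes, and marked 17, where chance marks about 9. Of these, 6 were WT 4 and 5 were KO 5.

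In WT 4, Krt1 was at 18.9 CPM against 6.01 to 8.08 CPM in the other WT libraries. Enam was at 326 CPM there against 50.2 to 84.8 CPM. Slc26a7 was at 404 CPM against 294 to 306 CPM, and Dmxl1 at 227 CPM against 167 to 172 CPM. Cldn4 was at 1.95 CPM against 3.72 to 3.93 CPM, and Slc2a1 at 87.2 CPM against 136 to 145 CPM. In WT 5, Gaa was at 96.4 CPM against 70.3 to 71.8 CPM in the other WT libraries, and Odam at 17863 CPM against 23793 to 24515 CPM. In WT 3, Ifit1 was at 0.811 CPM against 1.04 to 1.07 CPM.

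In KO 5, Mfap4 was at 54.0 CPM against 32.2 to 34.9 CPM in the other KO libraries, and Ndufa11 at 134 CPM against 60.2 to 67.2 CPM. Tyms was at 18.8 CPM there against 14.1 to 14.8 CPM, and Plin4 at 0.676 CPM against 0.109 to 0.184 CPM. Tsix was at 0 CPM in KO 5 against 0.164 to 0.184 CPM. Over all libraries together Tsix had 22 reads and Plin4 had 66, so both of these gaps rest on few reads. In KO 4, Smpd3 was at 62.8 CPM against 67.9 to 68.7 CPM, Slc8a2 at 3.04 CPM against 1.70 to 1.86 CPM, and Ambn at 27385 CPM against 38163 to 38787 CPM.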

How the results depend on the processing

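The keratinocyte covariate, the GC and length correction, the fit without KO 1 and KO 5 and the adjusted p of 0.1 were chosen after the data were examined. The count of changed genes (5) moved most. It was 0 at an adjusted p of 0.01 (edgeR, 2541 genes at an unadjusted p of 0.05) and 99 at 0.1. It was 2 (0 higher, 2 lower) with library totals and 4 (1 higher, 3 lower) with DESeq2 size factors. DESeq2's Wald test gave 465 genes (298 higher, 167 lower, 317 without an adjusted p), voom 1073 (704 and 369) and no filter 241 (180 and 61). The odontoblast covariate left 0 (684 at an unadjusted p of 0.05), the Xist covariate 1, 1 surrogate variable gave 101, the keratinocyte covariate 1125, the GC and length correction 15, and leaving out KO 1 and KO 5 gave 11. The cause was not tested. Leaving out 1 library gave 0 to 55 genes, a Wdr72 log2 fold change of -3.21 to -2.15 and 10 to 13 lists.

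The replicate numbers 3, 4 and 5 did not pair the libraries (correlations of deviations -0.14, -0.092 and -0.12). A replicate block over those 6 libraries gave 1 gene, Wdr72, and the same 6 libraries without the block also gave 1. Wdr72 passed 0.05 in the block fit at -3.42 and in those 6 libraries without the block at -3.35, both of which leave out KO 1. It also passed without KO 1 alone at -3.21, in DESeq2 at -2.44, in voom at -2.62 and with the keratinocyte covariate at -4.47.

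The count of lists (12) was 0 with an estimated correlation, 6 with the Xist covariate, 14 with DESeq2's Wald test, 15 with the GC and length correction and 17 with no filter. The keratinocyte and pulp mesenchyme lists each passed in 24 of 25 alternatives run with the preset correlation. With an estimated correlation neither passed (adjusted p = 0.48 and 0.57 in camera). Among the 25, each failed in 1 fit. The first did not with its own covariate, nor the second with the odontoblast covariate (median 0.21, adjusted p = 0.79). Camera's direction turned for the respiratory chain list, at a median of -0.0065 with voom, -0.072 with the Xist covariate, -0.039 with 1 surrogate variable, -0.021 without KO 5 (the lowest of -0.021 to 0.31 over left-out libraries) and -0.11 without KO 1 and KO 5. It turned for ribosomal proteins at 0.025 with the Xist covariate and -0.035 without KO 1 and KO 5, and for mitochondrial genes at 0.052 with the odontoblast covariate and 0.016 with the GC and length correction. With the odontoblast covariate the odontoblast list was at -0.075 and the neutrophil list at 1.40, and the erythroid (1.28), muscle (0.67) and cell cycle lists (0.38) newly passed, and with its own covariate the keratinocyte list was at 0.029. A list that serves as covariate is removed by construction, and since the odontoblast and keratinocyte means do not overlap between WT and KO, these covariates also take up the genotype and their fits bear on no explanation. Of 2150 alternative values for 83 other named genes, 59 no longer passed the threshold, 96 newly passed it, and 56 changed sign, of which 0 passed before or after. Camera's direction turned in 85 of 874 alternative list values. List tests were not run for the fit without robust dispersion, which does not enter camera. At this depth and spread, 23.4% of 1.5-fold changes were recovered in the simulation, whose genes varied independently.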

Other observations

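The tests of a Wdr72 transcript from the targeted allele, of keratinocyte genes varying together, of odontoblast against mesenchyme genes and of KO 5 alone were chosen after the results were seen, as were the GC and length correction and the margin by which a value had to pass its bound; the others were set before. The genes in the next paragraph were also chosen after their values were seen.

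At an adjusted p of 0.1, 63 genes were higher and 36 lower in KO. Among the lower ones were Inhba, the activin A subunit, at 130 ± 50.7 CPM in WT and 45.3 ± 10.9 CPM in KO, Ly6d, at 24.995 ± 11.2 and 6.43 ± 2.56 CPM, and Aqp3, a water and glycerol channel, at 13.1 ± 4.10 and 5.36 ± 0.796 CPM. Among the higher ones were Socs3, which restrains cytokine signalling, at 15.1 ± 1.28 and 36.5 ± 13.3 CPM, the receptor chain Il4ra at 30.1 ± 6.45 and 90.2 ± 40.6 CPM, and the acute phase gene Serpina3n at 2.61 ± 1.07 and 11.002 ± 4.75 CPM. Col6a2, a collagen VI chain, was at 109 ± 14.8 and 203 ± 39.2 CPM, Fmod at 36.8 ± 6.23 and 60.8 ± 8.35 CPM, and Igfbp5 at 647 ± 73.6 and 1060 ± 106 CPM. Odaph, a gene of enamel mineralisation, was at 34.1 ± 6.61 and 70.3 ± 19.2 CPM. No list was made for these genes before the data were examined.

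Other splits of the 8 libraries bear on both counts. Of the 35 splits into 4 and 4, 1, the real split itself, gave as many as its 5 changed genes. The highest of the others was 0. A share of 1 in 35 is the smallest that these splits can give. The count was also 0 without WT 2, WT 3, KO 3 or KO 4. The real split thus ranked first, but chance is not excluded for that count. For gene lists, 7 of the 35 splits gave as many as the 12 of the real split, and the highest of the others was 14, so chance cannot be excluded for the number of lists.

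Wdr72 reads remained in the KO libraries, most of them in KO 1. On 100 genes chosen without it, KO 1 had a median position of 0.329 on a scale from 0 (the other KO libraries) to 1 (WT), while KO 3, 4 and 5 placed the same way lay at 0.390, 0.287 and -0.434 and the WT libraries at 0.431 to 1.05. For Wdr72 itself KO 1 lay at 0.349 on such a scale, near its position on the 100 genes, as tissue with an intact gene would give. On those genes, however, KO 3 lay above KO 1. Tissue with an intact Wdr72 gene in KO 1, or a wrong label, therefore cannot be told apart from the spread between libraries. The bounds set beforehand, a position at or below the highest other KO library and one under 0.5, were met. They were met by less than that spread (SD 0.449 over KO 3, 4 and 5 and 0.289 over the WT libraries). A transcript made by the targeted allele may also leave such reads. The highest KO level was 6.44 times the lowest, against 1.89 times in WT, which counts per gene cannot assign to either source.

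Oral keratinocyte genes were lower in KO, among the abundant ones Krt6a at 607 and 439 CPM and Krt10 at 184 and 97.2 CPM in WT and KO. GC content and gene length argue against themselves as the whole cause, since the list's median was -1.20 after their correction against -1.03 before. A candidate explanation is that less oral epithelium was carried over into the KO dissections: within groups the 16 members varied together with a mean correlation of 0.334, above the 0.091 that 95% of 10000 random lists matched on expression stayed under, though a shared programme in 1 cell type would vary together as well. None of the 19 genes is in another list, and 11 tested members had a mean above 10 CPM in WT and 11 in KO. With Xist as a covariate the median was -0.61, past the bound set beforehand (-0.52) by 0.092. The margin was 0.22, an SE taken from the spread over the 16 members in the main fit. That SE treats members that vary together as independent and does not measure the spread between libraries. The comparison thus cannot decide on the sex makeup of the libraries, which stays open. An effect of the genotype itself was not tested apart from these explanations.

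Pulp mesenchyme genes were higher in KO. Neither GC content and length nor KO 5 alone accounts for it: the median of the pulp mesenchyme list was 0.45 after the correction and 0.34 without KO 5, against 0.39 before. A larger share of odontoblasts and other non-epithelial cells could raise these genes and cannot be told apart with 4 libraries per group: the mean log2 CPM of the whole odontoblast list was 8.94 ± 0.17 in WT and 9.34 ± 0.10 in KO (exact permutation p = 0.0286, adjusted p = 0.20), beside 6.33 ± 0.21 and 6.73 ± 0.17 for the pulp mesenchyme list (exact permutation p = 0.057, adjusted p = 0.22). Against Dspp, Dmp1, Phex and Nes alone, picked after the results were seen, the pulp mesenchyme mean moved by 0.42 in KO (exact permutation p = 0.20), and the mean of those 4 odontoblast genes itself differed by -0.023 (exact permutation p = 0.97), with Dspp at 13685 and 13052 CPM in WT and KO. An effect of the genotype on these cells stays open and untested.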
